A study of Mus musculus with 12 samples.

How the data were processed

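Primordial germ cells were isolated by the authors from mouse embryos, and 12 libraries were sequenced on an Illumina HiSeq 2000, per the labels' protocols. RNA came from 400 to 5000 cells for the E9.5, E11.5 and E13.5m samples and from 500 to 2000 cells for the Tet1-KO samples and the other E13.5 wild-type samples. Per the labels' protocols, cDNA was amplified with a low-input kit (2 to 70 ng) and sheared by sonication. Amplification from few cells adds noise at low levels.

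The submitters' processing notes name Bowtie, TopHat 1.3.1, Cufflinks and Cuffdiff in versions 1.2.1 and 1.0.3, and the build mm9. The authors deposited 4 Cuffdiff tables with 1 FPKM value per group (fragments scaled to transcript length and to the mapped total), per the file headers. Replicates were pooled into each FPKM value by the authors. Each table gives a p-value and a q-value or FDR made by the authors and deposited as such. The test statistic in the 3 stage tables is a score deposited by the authors. The stage tables have 22552 rows each and the knockout table has 16394. Of the FDR values for the knockout, 2182 exceed 1, with a maximum of 1.06, and 22 gene names read as calendar dates and were never named. Column totals in FPKM were 611167 at E9.5 and 765955 at E11.5 in one table and 775559 in wild type and 577828 in Tet1-KO in another. Library depth is not given by these values, so no counting interval was computed.

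Samples were grouped by title, age and genotype. The stage tables name a group E13.5f that no sample title carries, and it was used as the table names it. The E11.5 columns of the 3 stage tables differ by constant factors (0.870 and 0.976 to reach the E13.5f table), which set the common scale; tests were made only within tables, apart from the difference of log2 ratios below.

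Calls were the authors' own at their threshold of 0.05, over rows with a completed test. The log2 ratio was computed again from the 2 FPKM values, and its SE as the ratio divided by the deposited statistic, or by the normal deviate of the deposited p-value in the knockout table, where this deviate was above 0.05. No log2 ratio was given for a gene listed at 0 in a group. Changes used for ranking and for list medians were log2(FPKM + 1), which understates changes of low genes. Differences between E13.5m and E13.5f were tested with a normal two-sided test and Benjamini-Hochberg adjustment; the shared E11.5 libraries were ignored, which makes the test conservative. In the simulation of shared libraries 60 percent of the smaller variance was given to E11.5, and 40.0 percent to wild type for the Tet1-KO and E13.5f pair, each over 100 draws.

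Before the data were examined, 23 gene lists, the main tests and the rule for named genes were set. The test of the calls of each table relative to its median, the overlap with the E13.5m table and most tests of explanations were added later. The lists cover pluripotency and PGC identity, gonadal germ cells and the piRNA pathway, meiosis, the male programme, oogenesis, DNA and histone methylation, imprinting, the cell cycle and its inhibitors, migration, retinoic acid and BMP response, metabolism, apoptosis, stress, sex markers and 6 kinds of other cells. Members were matched by symbol, with older symbols from a reference gene table of GRCm38.p6 used for names only. The rule named Tet1, the 10 largest rises and 10 largest falls among called single-symbol genes at 5 FPKM or more, up to 4 members of each list by size of change, and all sex markers. A list median was placed among 10000 random lists matched on mean level in 20 bins. Exon lengths came from GENCODE annotation of another build, matched by symbol for 98.7 percent of genes, with no coordinates used.

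The test relative to the median was tested on simulated data. With 200 genes changed by 4 on the log2 scale, it recovered 93.5 percent in the E9.5 to E11.5 simulation of 10039 genes and 96.0 percent in the Tet1-KO simulation of 10858 genes, where 6.34 percent of calls were false. With changes of 2 it recovered 54.0 and 75.0 percent. These simulations changed 200 genes and set a common shift of 0.3. Among the deposited Tet1-KO calls 899 of 1010 fell. A fall of so many genes can move the median itself and was not simulated. The false share of 6.34 percent therefore cannot be carried over to the Tet1-KO calls relative to the median. Alternatives were a threshold of 0.01, adjustment computed again, a minimum of 1 FPKM, a minimum log2 change of 1, centring, 1 row per symbol and a pseudocount of 0.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.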

Results

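Messenger RNA was profiled in mouse primordial germ cells (PGCs), the embryonic precursors of eggs and sperm, from C57BL/6 embryos. The series holds 12 libraries. Wild-type cells were taken at embryonic day 9.5 (E9.5, 2 libraries), at E11.5 (2 libraries) and at E13.5, where 3 libraries carry the label E13.5m and 3 further wild-type libraries carry no sex in their labels. Cells lacking Tet1, which encodes an enzyme that oxidises 5-methylcytosine in DNA, were taken at E13.5 (2 libraries). The authors deposited 4 comparison tables, each with 1 pooled FPKM value per group and no value per library, so no spread between replicates can be shown for a level and the sequencing depth is unknown. The error given with a log2 ratio is the standard error (SE) that the deposited test implies. Nothing in the labels says whether libraries of a group came from separate embryos, so the deposited tests measure the spread between these libraries, which may be technical. The E13.5f and E13.5m names are used as the tables and labels give them.

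The first comparison asked how germ cells changed between E9.5, when they migrate, and E11.5, when they populate the gonad. Dazl, an RNA-binding protein gene of germ cells (chromosome 17, 50418718 to 50432924, build mm9), rose from 2.24 to 355 FPKM, a log2 ratio of 7.31 ± 0.84 (SE). Ddx4, the vasa helicase gene (chromosome 13, 113388540 to 113442518), rose from 10.3 to 176 FPKM, a log2 ratio of 4.09 ± 0.45 (SE). Asz1 of the piRNA pathway, which silences transposons, rose from 1.44 to 157 FPKM. In the list of gonadal germ cell and piRNA pathway genes 12 of 23 tested members rose, 0 fell and 11 were not called. Adjusted over the list alone, 19 members rose.

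Of 30 tested pluripotency and PGC identity genes 8 rose, 1 fell and 21 were not called; adjusted over the list alone, 8 rose and 3 fell. Dppa4 rose from 44.9 to 469.8 FPKM, Dppa5a from 146 to 1037 FPKM and Zfp42 from 39.3 to 206 FPKM. The typical member did not rise with them: the list median was 0.01 on the log2(FPKM + 1) scale, at percentile 0.04 of random lists. Of 35 tested meiosis genes 9 rose and 0 fell, and 9 rose when adjusted over the list alone. Among them were Smc1b, a meiotic cohesin gene, with a log2 ratio of 5.03 ± 0.95 (SE), and Hormad1, a chromosome axis gene, with 3.99 ± 0.91 (SE). In the male germ cell list 5 of 9 tested members rose (8 adjusted over the list alone), among them the Nodal pathway gene Lefty2, from 9.11 to 149 FPKM. In the oogenesis list 3 of 10 rose (3 adjusted over the list alone), led by Sohlh2, from 1.46 to 114 FPKM.

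Embryonic globin genes gave the 3 largest falls in log2(FPKM + 1) among called genes at 5 FPKM or more. Hbb-y (chromosome 7, 111000267 to 111001721) fell from 869 to 10.8 FPKM, a log2 ratio of -6.33 ± 0.68 (SE), Hbb-bh1 from 494 to 2.10 FPKM and Hba-x from 625 to 9.89 FPKM. Of 14 tested blood and macrophage markers 6 fell, 0 rose and 8 were not called; adjusted over the list alone, 6 fell and 2 rose. Imprinted genes, expressed from 1 parental copy, fell in 6 of 31 tested cases and rose in 0; adjusted over the list alone, 7 fell and 1 rose. Grb10 fell from 13.3 to 1.02 FPKM and Meg3 from 20.7 to 4.78 FPKM. Calls among glycolysis genes were split, with 3 of 19 rising and 3 falling (4 and 3 adjusted over the list alone). The glycolysis list as a whole lay low, with a median log2(FPKM + 1) change of -0.16, at percentile 0 of random lists. Ldha fell from 838 to 97.8 FPKM while Ldhb, the other lactate dehydrogenase subunit, rose from 83.7 to 389 FPKM. The D-type cyclin gene Ccnd2 fell from 18.3 to 1.96 FPKM.

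The authors' deposited table called 727 of 12904 tested genes between E9.5 and E11.5, 479 higher and 248 lower at E11.5. The median log2 ratio of genes at 1 FPKM or more in both groups was 0.32. Tested again relative to that median, a setting chosen after seeing the data that shifts all genes alike, 234 genes rose and 342 fell. In each table this test covered only genes with an SE, here 11787, and so left out genes at 0 FPKM in a group. Among those left out here were 31 called genes at 0 at E9.5, so part of the drop in rises is exclusion. Relative to the median, 8 germ cell and piRNA genes, 7 meiosis genes, 5 pluripotency genes, 2 male germ cell genes and 2 oogenesis genes rose, while 3 pluripotency genes, 6 blood markers and 7 imprinted genes fell. The median of the pluripotency list was 0.01 before and -0.31 after this shift was subtracted, with a mean of 0.45 before it.

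**Figure D1:**
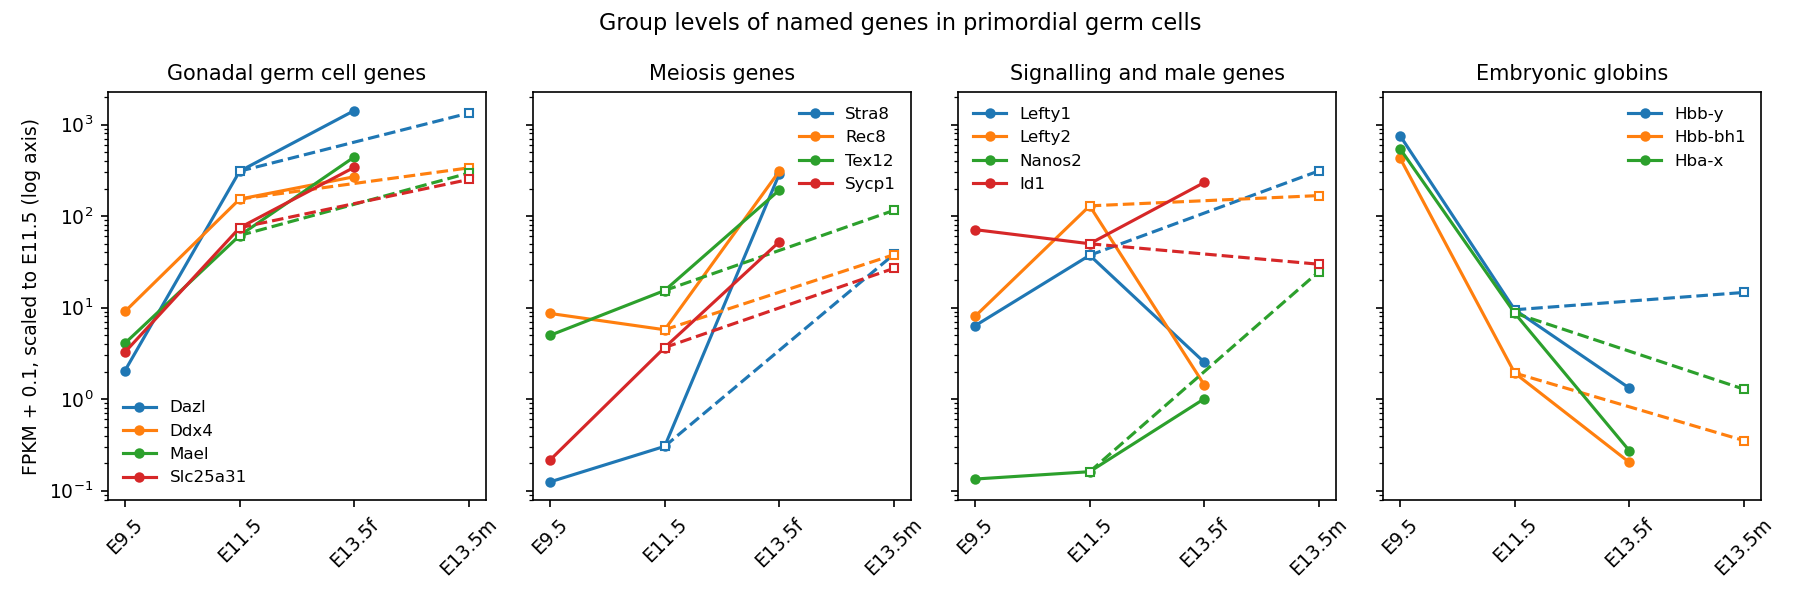
Pooled FPKM of named genes (log axis, 0.1 added) at E9.5, E11.5, E13.5f (solid lines, filled circles) and E13.5m (dashed lines, open squares), set to a common scale through the E11.5 values; no error can be drawn for pooled values. Dazl goes from 2.24 to 355 FPKM between E9.5 and E11.5 in its own table, and Stra8 reaches 288 FPKM at E13.5f.

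The second comparison followed the cells from E11.5 to E13.5f. The meiosis list rose: 22 of 36 tested members rose, 0 fell and 14 were not called, with 23 rising when adjusted over the list alone. Stra8, which germ cells need to begin meiosis (chromosome 6, 34870959 to 34889342), rose from 0.205 to 288 FPKM, a log2 ratio of 10.46 ± 1.15 (SE). Rec8, the meiotic cohesin (chromosome 14, 56237002 to 56244232), rose from 5.63 to 309 FPKM, a log2 ratio of 5.78 ± 0.52 (SE). Meioc, listed as Gm1564, rose from 0.0503 to 22.5 FPKM and Tex12, a synaptonemal complex gene, from 15.3 to 192 FPKM.

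The germ cell and piRNA list rose in 12 of 26 tested members and fell in 0, with 17 rising when adjusted over the list alone. Tex101 rose from 17.2 to 306 FPKM, Brdt, a testis bromodomain gene, from 6.20 to 87.7 FPKM, and Dazl from 309 to 1421 FPKM. Of 23 tested retinoic acid and BMP response genes 5 rose and 0 fell, and 15 rose when adjusted over the list alone. Msx1 rose from 21.2 to 208 FPKM and Id1 from 49.7 to 233 FPKM. Oogenesis genes rose in 3 of 13 cases and fell in 1, the same counts as adjusted over the list alone; Figla, a transcription factor of the oocyte, rose from 0.220 to 6.72 FPKM. Imprinted genes rose in 6 of 27 tested cases and fell in 0, with 6 rising when adjusted over the list alone, among them Dlk1, from 0.142 to 6.14 FPKM.

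Lefty2, a gene of Nodal signalling, fell from 129 to 1.33 FPKM, a log2 ratio of -6.61 ± 0.69 (SE), as did Lefty1 (chromosome 1, 182865169 to 182868532) from 37.2 to 2.43 FPKM and Tdgf1 from 37.8 to 0.845 FPKM. The male germ cell list, which holds them, had 2 of 13 members rising and 4 falling (6 and 4 adjusted over the list alone), with a median of 0.79 and a mean of -0.66. Of 28 tested pluripotency and PGC identity genes 5 fell and 2 rose (6 and 2 adjusted over the list alone); Nr0b1 fell from 22.2 to 2.08 FPKM and Esrrb from 37.5 to 7.28 FPKM. Glycolysis genes fell in 3 of 18 tested cases and rose in 0, with 4 falling and 1 rising when adjusted over the list alone, led by Hk1, from 32.8 to 5.23 FPKM. Y-linked Eif2s3y fell from 46.5 to 0.178 FPKM and Ddx3y from 2.17 to 0.0120 FPKM. Among markers of other cells, Irx3 of the female gonad soma list rose from 1.72 to 8.46 FPKM and Krt18 of the epithelium list from 20.1 to 68.6 FPKM, while Pax8 of the epithelium list fell from 5.38 to 1.37 FPKM and Esam of the endothelium list from 8.81 to 0.894 FPKM. In all, 2 of 4 endothelium and 2 of 10 blood markers fell (3 and 2 adjusted over the list alone).

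The authors' deposited table called 1496 of 12448 tested genes between E11.5 and E13.5f, 1163 higher and 333 lower at E13.5f. The median log2 ratio was 0.19, and relative to it 817 genes rose and 487 fell. Relative to the median, 18 meiosis genes and 9 germ cell and piRNA genes rose, 5 glycolysis genes fell, and 1 male germ cell gene rose and 4 fell. The meiosis genes Sycp3 and Syce2, named after their values were seen, had no completed test in this table.

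The third comparison followed the cells from E11.5 to E13.5m. Nanos2, an RNA-binding protein gene of male germ cells (chromosome 7, 19572872 to 19574311), rose from 0.0626 to 25.3 FPKM, a log2 ratio of 8.66 ± 1.46 (SE). Lefty1 rose from 38.1 to 319 FPKM, a log2 ratio of 3.07 ± 0.47 (SE). In the male germ cell list 4 of 12 tested members rose and 0 fell, and 5 rose when adjusted over the list alone. The homeobox genes Hesx1, from 0.230 to 58.4 FPKM, and Otx2, from 0.650 to 44.3 FPKM, were among the 10 largest rises in log2(FPKM + 1) of called genes at 5 FPKM or more, with Pmaip1, a BH3-only gene of the apoptosis pathway, from 1.99 to 69.2 FPKM.

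Meiosis genes rose here too, in 9 of 34 tested cases with 0 falling and 10 rising when adjusted over the list alone. Stra8 rose from 0.210 to 39.0 FPKM and Rec8 from 5.76 to 38.7 FPKM. The germ cell and piRNA list rose in 8 of 25 cases, with 16 rising when adjusted over the list alone; Dazl rose from 317 to 1366 FPKM and Mael from 62.7 to 302 FPKM. Of 29 tested pluripotency and PGC identity genes 6 fell and 1 rose (10 and 2 adjusted over the list alone), among them Klf2, from 175 to 41.9 FPKM, and Tfap2c, listed as Tcfap2c, from 189.7 to 48.4 FPKM. Glycolysis genes fell in 3 of 18 cases (5 adjusted over the list alone), Hk1 from 33.6 to 5.63 FPKM. The 10 largest falls by the same measure included Apoe, an apolipoprotein gene, from 296 to 15.2 FPKM, and Serpinb9b, from 53.5 to 1.55 FPKM.

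Some markers of other cells were called as well. Amh, a Sertoli cell hormone gene, rose from 0.129 to 4.01 FPKM, the 1 call among 14 tested male gonad soma markers, with 6 rising and 1 falling when adjusted over the list alone. Rspo1 of the female gonad soma list rose from 0.471 to 7.38 FPKM and Krt19 of the epithelium list from 0.200 to 4.08 FPKM, while Pax8 of the epithelium list fell from 5.52 to 0.655 FPKM, Esam of the endothelium list from 9.03 to 0.503 FPKM and Sparc of the mesenchyme list from 116 to 30.4 FPKM. Y-linked Eif2s3y rose from 47.6 to 271 FPKM and Uty from 0.385 to 3.30 FPKM. The authors' deposited table called 601 of 12311 tested genes, 362 higher and 239 lower at E13.5m. The median log2 ratio was 0.02, and relative to it 362 rose and 250 fell.

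No deposited table compared E13.5m with E13.5f. The difference of the 2 log2 ratios against E11.5 was therefore tested per gene, with SEs from the deposited statistics and Benjamini-Hochberg adjustment over 10677 genes. Genes at 0 FPKM in a group had no SE and were left out, among them Y-linked Kdm5d, at 0 FPKM in E13.5f. The test gave 13 genes higher in E13.5m and 5 higher in E13.5f. At an unadjusted p under 0.05 the split was 131 and 270. Lefty1 was higher in E13.5m by 7.01 ± 0.82 (SE) on the log2 scale, at 312 against 2.43 FPKM on the common scale, and Lefty2 by 6.98 ± 0.83 (SE). Tdgf1, the Nodal co-receptor gene, was higher by 4.94 ± 0.99 (SE) and Pmaip1 by 6.20 ± 0.99 (SE). Y-linked Eif2s3y stood at 264 FPKM in E13.5m and 0.178 FPKM in E13.5f. Higher in E13.5f were Rec8, with a log2 E13.5m over E13.5f of -3.04 ± 0.76 (SE), Id1, with -2.97 ± 0.73 (SE), and Smox, with -1.07 ± 0.22 (SE). The retinoic acid and BMP response list had a median of -1.26 over 17 tested members, with 1 passing, higher in E13.5f, and 5 passing when adjusted over the list alone. For Stra8 the difference was -2.92 ± 1.64 (SE) and did not pass this test, which counts the E11.5 error in both ratios. With each table centred on its median the split became 18 and 1, with Smox the gene that stayed higher in E13.5f. If E13.5f holds the E13.5 wild-type libraries without a sex label, it comes from the set made from 500 to 2000 cells. E11.5 and E13.5m come from the set made from 400 to 5000 cells. Sex, and stage from E11.5 to E13.5f, could then not be told apart from library set.

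Changes after E11.5 overlapped between E13.5f and E13.5m. Of 11646 genes tested in both, 212 rose in both, where independent lists would share 29.9, and 97 fell in both, where independent lists would share 6.16. Only 4 genes, named after their values were seen, were called in opposite directions: Eif2s3y, Irgm1, Lefty1 and Lrrfip1 fell at E13.5f and rose at E13.5m. Eif2s3y is Y-linked, and the unknown mix of sexes in the E11.5 libraries bears on both of its calls. Across 9310 genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.77 and a covariance of 1.06. Simulated changes with no effect but the same E11.5 libraries gave an r of 0.52 and a covariance of 0.40. The E11.5 libraries could not be split, and part of the excess may come from them.

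**Figure D2:**
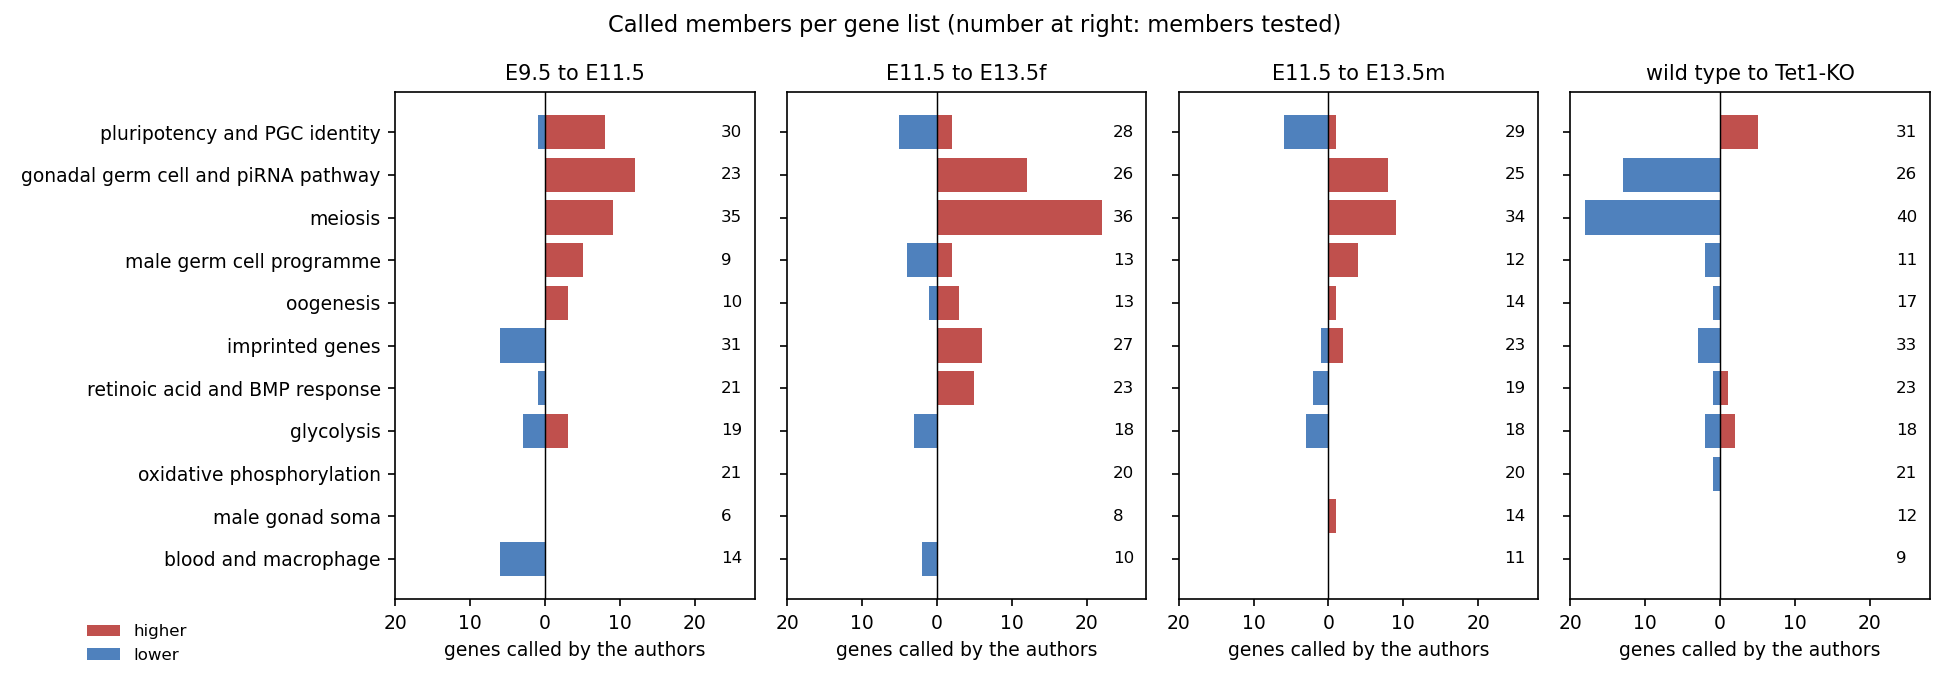
Number of genes the authors called higher (red, to the right) or lower (blue, to the left) in the second group of each comparison, for 11 of the 23 gene lists, with the number of tested members at the right of each panel. The meiosis list has 22 calls to the right at E13.5f and 18 to the left in Tet1-KO.

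The last comparison asked what loss of Tet1 changes at E13.5. Tet1 itself (chromosome 10, 62267317 to 62342762) was at 6.36 FPKM in wild type and 0.218 FPKM in Tet1-KO, a log2 ratio of -4.87 ± 0.67 (SE), with an FDR of 1.55e-10 in the authors' deposited table. Meiosis genes were lower in the knockout: 18 of 40 tested members fell, 0 rose and 22 were not called, with 28 falling when adjusted over the list alone. Stra8 fell from 302 to 32.2 FPKM, a log2 ratio of -3.23 ± 0.41 (SE). Meiob, listed as 4930528F23Rik, fell from 21.8 to 1.41 FPKM, and Prdm9, which places recombination sites, from 5.62 to 0.671 FPKM. Meioc, listed as Gm1564, fell with a log2 ratio of -3.58 ± 0.53 (SE).

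Germ cell and piRNA genes fell in 13 of 26 tested cases and rose in 0, with 17 falling when adjusted over the list alone. Tex101 (chromosome 7, 25453030 to 25457069) fell from 321 to 29.2 FPKM, Brdt from 91.6 to 6.48 FPKM and Slc25a31 from 358 to 69.1 FPKM. Among called genes at 5 FPKM or more, the largest fall in log2(FPKM + 1) was that of Tex13 on chromosome X, from 48.8 to 0.556 FPKM. Ccnd1 fell from 41.2 to 11.7 FPKM and Sohlh2 from 326 to 113 FPKM.

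Among pluripotency and PGC identity genes the calls were rises. Of 31 tested members 5 rose, 0 fell and 26 were not called, with 5 rising and 1 falling when adjusted over the list alone. Sox2 (chromosome 3) rose from 23.7 to 67.3 FPKM, Klf2 from 64.3 to 124 FPKM and Nr0b1 from 2.18 to 9.25 FPKM. In the DNA methylation list 3 of 25 fell and 1 rose (4 and 1 adjusted over the list alone): Tet1 and Uhrf1, a cofactor of maintenance methylation, fell, Uhrf1 only before the median shift below was subtracted, and Parp1 rose from 69.7 to 139 FPKM. Imprinted genes fell in 3 of 33 cases and rose in 0 (3 and 2 adjusted over the list alone), Dlk1 from 6.37 to 0.896 FPKM. Glycolysis genes were split, 2 of 18 rising and 2 falling (3 and 3 adjusted over the list alone), with Hk1 rising from 5.45 to 19.2 FPKM.

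The authors' deposited table called 1010 of 16394 tested genes, 111 higher and 899 lower in Tet1-KO. The median log2 ratio was -0.38, and relative to it 264 genes rose and 233 fell, a balance towards which the subtraction itself moves the calls. Relative to the median, 14 meiosis genes and 6 germ cell and piRNA genes fell and 7 pluripotency genes rose. The pluripotency list had a median of -0.04 before and 0.34 after the shift was subtracted. The imprinted list then had 2 rises and 1 fall, and the glycolysis list 3 rises and 0 falls.

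**Figure D3:**
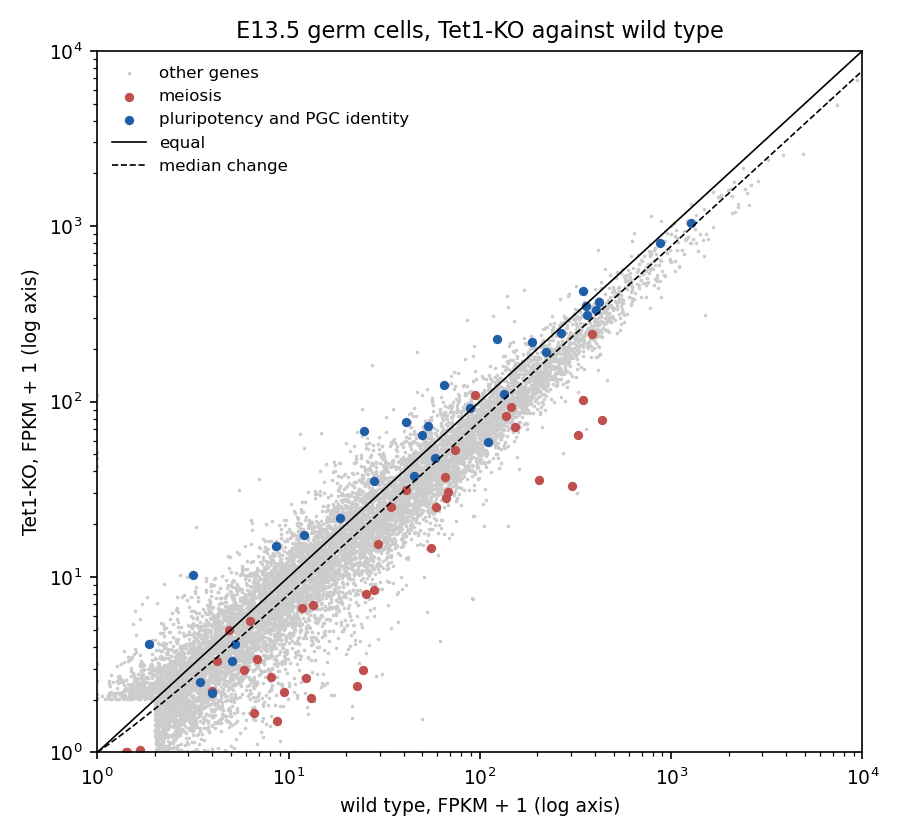
FPKM plus 1 in wild type (x, log axis) and Tet1-KO (y, log axis) for genes at 1 FPKM or more in either group, with meiosis genes in red, pluripotency and PGC identity genes in blue, a solid line for equal levels and a dashed line for the median log2 ratio of -0.38; points are pooled values with no error. Of the 35 meiosis genes at 1 FPKM or more in both groups, 3 lie above the dashed line.

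Genes that fell in Tet1-KO were often genes that rise between E11.5 and E13.5f. Of 11973 genes tested in both tables, 356 fell in Tet1-KO and rose at E13.5f, where independent lists would share 69.1, and 35 rose in Tet1-KO and fell at E13.5f, where independent lists would share 2.26. With both tables centred on their medians these counts were 122, where independent lists would share 12.7, and 86, where independent lists would share 7.89. These 2 tables are not independent. The E13.5f column and the wild-type column of the knockout table had a Pearson r of 0.999 across 10996 genes, which are not independent replicates. Their log2 ratio had quartiles of -0.06 and -0.04, against -0.11 and 0.56 for E13.5f over E13.5m. Y-linked Eif2s3y stood at 0.178 FPKM in E13.5f, 0.137 FPKM in wild type and 0.0296 FPKM in Tet1-KO, against 264 FPKM in E13.5m. By this marker the wild-type and Tet1-KO columns held little RNA of male cells, although their labels give no sex. The series design gives E13.5f 3 libraries, and the 3 E13.5 wild-type libraries without a sex label are the only ones under no other stage name. The E13.5f and wild-type columns may therefore well hold the same libraries. Across 9545 genes the log2 ratios of the 2 tables had a Pearson r of -0.60 and a covariance of -0.60, and simulated changes with no effect but 1 set of libraries in both columns gave an r of -0.27 and a covariance of -0.12. The E13.5m table shares no labelled group with the knockout table. There, as an alternative chosen after seeing the data, 123 genes fell in Tet1-KO and rose at E13.5m, where independent lists would share 21.3, and 23 rose in Tet1-KO and fell at E13.5m, where independent lists would share 1.69. With both tables centred the counts were 53, where independent lists would share 5.38, and 41, where independent lists would share 4.19.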

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

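Of the tests below, those on transcript length were set before their result was seen; the tests on scale, male cells, germ cell share, stage, erythroid RNA and neighbouring somatic RNA were chosen after the results they bear on had been seen.

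Levels differed between E13.5f and E13.5m for 18 genes, by the test of the difference of log2 ratios. The rule for named genes took 14 of them. The E11.5 value is shared by both ratios and cancels. A change from E11.5 particular to each sex was therefore not tested. The log2 E13.5m over E13.5f was -3.04 for Rec8, -2.97 for Id1, -2.93 for Phlda2 and -1.07 for Smox. It was 10.53 for Eif2s3y, 7.01 for Lefty1, 6.98 for Lefty2, 6.20 for Pmaip1, 9.15 for Krt17, 4.27 for 2410004A20Rik, 4.94 for Tdgf1, 5.11 for Irgm1, 3.07 for Lrrfip1 and 3.12 for Dgka. After centring each table, the adjusted p became 0.0643 for Rec8, 0.0587 for Id1 and 0.0879 for Phlda2, with log2 differences of -2.86, -2.80 and -2.76 and unchanged SEs of 0.76, 0.73 and 0.75, because the medians of the tables differ by -0.17.

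Far more genes were lower than higher in Tet1-KO. Transcript length was argued against as the whole cause: the median log2 ratio was below 0 in each of 10 length bins, the highest being -0.27. After the median was subtracted 46.9 percent of calls fell, against 89.0 percent before, but the subtraction moves calls towards balance by construction, so it decides nothing. The scale of the 2 FPKM columns and a true fall of many RNAs cannot be told apart, because the pooled values hold no reference for scale.

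For the lower meiosis genes in Tet1-KO, scale as the whole cause was argued against, with 14 members still falling after the median was subtracted. Male cells in the Tet1-KO libraries were argued against, since the Y-linked genes Ddx3y and Eif2s3y summed to 0.0110 percent of their E13.5m level. A lower share of germ cells stays open. The pluripotency and PGC identity list lay 0.30 above the median of all genes (quartiles 0.10 and 0.80), while the meiosis list lay at -0.89 relative to it. The pluripotency list also had medians of -0.37 from E11.5 to E13.5f and -0.52 to E13.5m, so it cannot separate stage from germ cell share. The gonadal germ cell and piRNA list fell in 13 of 26 cases, with a median of -0.90 and of -0.52 after centring. The gonad soma lists had 0 calls, with medians of 0.18 (female, percentile 96.6 of random lists) and 0.16 (male, percentile 97.7). Of their members 4 of 9 and 8 of 12 were below 1 FPKM. A hypothesis that stays open is that the Tet1-KO cells may be nearer to an earlier stage: of genes that fell in Tet1-KO and were called at E13.5m, 99.2 percent rise from E11.5 to E13.5m, against 59.4 percent of all genes called there; a direct need for Tet1 at these genes and a difference in embryo age were not tested.

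Globin genes were high at E9.5. RNA of erythroid cells stays open as a candidate source: of Slc4a1 and Alas2, genes of red cells in the blood and macrophage list, 1 fell by E11.5, Slc4a1 from 3.57 to 0.357 FPKM, while Alas2 was at 0.505 and 0.364 FPKM and was not called, against 869 FPKM of Hbb-y at E9.5. RNA of neighbouring somatic cells also stays open: the share of tested members that fell was at most 25 percent in a list, with 2 of 8 epithelium, 0 of 4 endothelium and 0 of 7 mesenchyme markers falling, 4 of the 7 below 1 FPKM. The epithelium list had a median of -0.94, at percentile 0.03 of random lists, while the endothelium list went the other way, with 2 of 4 rising and a median of 1.49 at percentile 99.7. For the globin genes no biological explanation was tested.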

How the results depend on the processing

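The alternatives that tested the calls of the 4 tables again relative to the median, and the use of the E13.5m table for the overlap, were chosen after seeing the data. Centring of the E13.5m against E13.5f difference was planned. At a threshold of 0.01 the calls numbered 348 from E9.5 to E11.5, 699 from E11.5 to E13.5f, 296 from E11.5 to E13.5m and 371 in Tet1-KO, the E13.5m against E13.5f difference kept 11 genes in number, and the overlap between E13.5f and E13.5m in the same direction was 118 genes; a stricter threshold lowers such counts by construction. Tested relative to the median, Tet1-KO calls numbered 497, and the share of calls that fell was 59.4 percent from E9.5 to E11.5, 37.3 percent from E11.5 to E13.5f and 46.9 percent in Tet1-KO. The overlap of Tet1-KO calls with opposite calls was 146 genes with the E13.5m table and 391 with the E13.5f table. Fewer genes were called at E13.5m, which lowers such a count. Among genes also tested in Tet1-KO, 345 rose and 236 fell at E13.5m, against 1141 and 319 at E13.5f. The 2 overlaps are therefore not to be compared as raw counts. Adjustment computed again, a minimum of 1 FPKM, a minimum log2 change of 1 and 1 row per symbol left the counts of calls of the 4 tables within 1.5 times their main values; for the E13.5m against E13.5f count and the overlaps this was run only for the minimum of 1 FPKM, with the same outcome. Centring reversed the sign of the median of the pluripotency and PGC identity list from E9.5 to E11.5 (-0.31 after centring) and in Tet1-KO (0.34). It also reversed that of the imprinted gene list in Tet1-KO (0.38) and of Pdgfra in Tet1-KO (0.12). The shift is a median of log2 ratios of genes at 1 FPKM or more, while these values are log2(FPKM + 1) changes, compressed at low levels. Pdgfra fell from 0.200 to 0.00478 FPKM, so its reversal comes from the unlike scales and is no rise. The imprinted list had a median of -0.001 before centring and 13 of 33 members below 1 FPKM, so the scales bear on it too. A pseudocount of 0.1 moved 111 log2 changes of named genes by more than their SE (by more than 1 where no SE was given) and left 329 within it; no pseudocount moved 113 and centring moved 31. Of the list medians, a pseudocount of 0.1 moved 23, centring 18 and the minimum of 1 FPKM 11 by more than 0.5 of their interquartile range. No paired analysis was possible because the tables hold 1 pooled value per group, although the labels give some groups the same replicate numbers. For the same reason no replicate was left out and no other split of the libraries was made. Depth is unknown, so genes near 0 FPKM cannot be called absent.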

Other observations

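The gene families in this paragraph were chosen by symbol after the data had been seen. Rhox genes, a cluster of homeobox genes on the X chromosome, rose from E9.5 to E11.5 in 8 of 22 tested cases and fell in 0, with a list median of 2.21 on the log2(FPKM + 1) scale, at percentile 100 of random lists; 7 rose relative to the median of all genes. From E11.5 to E13.5m, 2 of 23 fell, Rhox6 and Rhox9, and 0 rose, with a list median of -0.83 at percentile 0. From E11.5 to E13.5f 3 of 23 rose, Rhox1, Rhox7 and Rhox13, and 0 fell, with a median of 0.07 at percentile 29.0. In Tet1-KO 1 of 26 fell, Rhox13, with a median of -0.56 at percentile 0.43. Relative to the median of all genes 2 rose and 1 fell in Tet1-KO. The cluster includes near-identical copies, and how reads were shared between them is not given. The tubulin genes Tuba3a and Tuba3b, also close copies, rose from E9.5 to E11.5, to E13.5f and to E13.5m and fell in Tet1-KO. Tuba3a went from 10.3 to 339.5 FPKM between E9.5 and E11.5.

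Counts for the lists not described above follow, with counts adjusted over the list alone in parentheses. From E9.5 to E11.5, falls numbered 1 of 35 cell cycle genes (1), 1 of 18 migration genes (1), 1 of 19 apoptosis genes (1), 1 of 23 histone methylation genes (1, with 1 rise), 1 of 21 retinoic acid and BMP response genes (2, with 1 rise), 1 of 7 sex markers (2) and 2 of 8 epithelium markers (2), namely Krt8 and Cdx2. Rises numbered 1 of 22 DNA methylation genes (1), 1 of 9 cell cycle inhibitor genes (1), 1 of 15 stress genes (1) and 2 of 4 endothelium markers (3); relative to the median of all genes 0, 0, 0 and 1 rose, and 1 stress gene fell, Egr1 with a log2 ratio of -1.68 ± 0.63 (SE). Cuffdiff called 0 of 21 oxidative phosphorylation genes, 0 of 6 male gonad soma, 0 of 6 female gonad soma and 0 of 7 mesenchyme markers, with 1, 3, 4 and 3 at an unadjusted p under 0.05.

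From E11.5 to E13.5f, rises numbered 3 of 16 migration genes (3), 2 of 8 cell cycle inhibitor genes (2) and 1 of 6 female gonad soma markers (2), and falls numbered 1 of 17 DNA methylation genes (1), 2 of 4 endothelium markers (3), 2 of 10 blood markers (2) and 3 of 6 sex markers (6), each with the count adjusted over the list alone in parentheses. Calls went both ways for epithelium markers, where 2 of 12 rose and 1 fell (5 and 1), the cell cycle, where 1 of 32 rose and 2 fell (1 and 2), histone methylation, with 1 and 1 of 20 (1 and 1), apoptosis, with 1 and 1 of 17 (1 and 1), and stress genes, with 1 and 2 of 13 (1 and 2). Relative to the median of all genes, migration had 2 rises and 1 fall and the cell cycle 1 rise and 4 falls. Histone methylation then had 1 rise and 2 falls, epithelium markers 1 rise and 1 fall, cell cycle inhibitors 1 rise and sex markers 2 falls. Cuffdiff called 0 of 20 oxidative phosphorylation genes, 0 of 8 male gonad soma and 0 of 6 mesenchyme markers, with 2, 2 and 2 at an unadjusted p under 0.05.

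From E11.5 to E13.5m, falls numbered 3 of 16 migration genes (4), 2 of 19 retinoic acid and BMP response genes (3), 2 of 20 DNA methylation genes (2, with 1 rise), 1 of 4 endothelium markers (2) and 1 of 6 mesenchyme markers (1), with the counts adjusted over the list alone in parentheses. Rises numbered 2 of 16 apoptosis genes (2, with 1 fall), 1 of 14 oogenesis genes (2), 1 of 7 cell cycle inhibitor genes (1), 1 of 5 female gonad soma markers (1) and 2 of 6 sex markers (2). Calls went both ways for imprinted genes, with 2 rises and 1 fall of 23 (3 and 3), the cell cycle, with 1 and 1 of 32 (1 and 1), and epithelium markers, with 1 and 1 of 12 (1 and 1). Cuffdiff called 0 of 20 histone methylation genes, 0 of 20 oxidative phosphorylation genes, 0 of 14 stress genes and 0 of 11 blood markers, with 4, 0, 2 and 4 at an unadjusted p under 0.05.

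In Tet1-KO, falls numbered 2 of 11 male germ cell genes (3), 1 of 17 oogenesis genes (2), 2 of 23 histone methylation genes (2), 2 of 10 cell cycle inhibitor genes (2), 1 of 21 oxidative phosphorylation genes (3), 2 of 21 apoptosis genes (3, with 1 rise) and 2 of 8 mesenchyme markers (3), with the counts adjusted over the list alone in parentheses. The 2 mesenchyme markers, Pdgfra and Pdgfrb, were at 0.200 and 0.311 FPKM in wild type. Relative to the median of all genes these lists had 0, 1, 1, 1, 1, 0 and 1 falls, and the histone methylation and apoptosis lists had 1 rise each. The 2 male germ cell genes were Mov10l1, also in the germ cell and piRNA list, and Nanos2, at 0.809 FPKM in wild type. Prdm9, 1 of the 2 histone methylation genes, is also in the meiosis list. Calls went both ways for the cell cycle, where 1 of 35 rose and 2 fell (1 and 5; 2 and 1 relative to the median), for retinoic acid and BMP response, with 1 and 1 of 23 (1 and 2; 1 and 0 relative to the median), and for stress genes, with 1 and 2 of 16 (1 and 2; 2 and 1 relative to the median). Cuffdiff called 0 of 17 migration genes and 0 of 9 female gonad soma, 0 of 12 male gonad soma, 0 of 7 endothelium, 0 of 9 blood, 0 of 13 epithelium and 0 of 4 sex markers, with 4, 0, 3, 0, 0, 0 and 0 at an unadjusted p under 0.05.

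A hypothesis set before its result was seen concerned the X chromosome. If both X chromosomes are active in E13.5f cells, X-linked genes should be lower in E13.5m than autosomal genes by 0.3 or more on the log2 scale. The median log2 E13.5m over E13.5f was -0.62 for 331 X-linked genes and -0.21 for 8305 autosomal genes, a difference of -0.42, outside the range of -0.13 to 0.13 of 10000 random sets of autosomal genes. Single autosomes had medians from -0.28 to -0.14. From E11.5 to E13.5f the X-linked median lay 0.29 above the autosomal one, from E11.5 to E13.5m it differed by -0.08 (percentile 1.05 of the random sets), and in Tet1-KO it lay 0.03 above. The E11.5 libraries held Y-linked RNA, with Eif2s3y at 46.5 FPKM, so their mix of sexes bears on each comparison with E11.5. From E9.5 to E11.5, in that table's own scale, Eif2s3y went from 122 to 53.4 FPKM and Uty, which was called, from 2.72 to 0.432 FPKM. Ddx3y and Kdm5d were also lower at E11.5 and not called, while Zfy1 and Zfy2 were higher, at levels below 1 FPKM. A different mix of sexes at E9.5 and E11.5 was not tested. The X-linked medians fit with more X-linked RNA in E13.5f cells. Genes are not independent replicates, and X inactivation itself was not measured. Xist was at 0.0233 FPKM in E13.5f and untested.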
